A study of Micropterus salmoides with 24 samples.

How the data were processed

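RNA from head and trunk kidney of male largemouth bass was analysed in 24 libraries, 4 for each tissue and treatment. Per the labels' protocols, fish were kept 4 to a tank in 4 tanks of 38 L per treatment. The labels do not say which tank a sequenced fish came from, when it was sampled or in which run its library was sequenced. Per the labels' protocols, libraries were made from 250 ng of total RNA by poly(A) selection and a directional kit, with 10 cycles of amplification. No molecular identifiers are mentioned, so reads are not independent molecules and the limits given for counts of 0 cover counting error only.

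The deposited values are read counts per transcript contig, whole numbers that had not been normalized, with contigs at 0 left out of a library's list and filled in here as 0. Per the submitters' processing notes, cutadapt, SAMtools, DESeq and edgeR were used, without versions. The aligner, the counting step, the use of strand and the origin of the contigs are not given in the sources used here. The 78435 contigs carry identifiers of 3 kinds (25062 LMB_Assem, 45684 isotig and 7689 contig). The LMB_Assem contigs took 74.3% to 81.3% of the counts of a library. None of the identifiers matched the table of gene names used here (0 matches). Several contigs can stem from one gene, and contigs of near-identical sequence can share reads, so the value of any single contig is uncertain to that extent. For lack of gene names, the gene lists fixed beforehand and the cell type markers were not tested, and no check of contig length or GC content was made.

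Groups and replicate numbers come from the sample titles. Of the same-numbered pairs of trunk glyphosate and trunk Rodeo libraries, 4 of 4 had deviations from their group means that correlated above 0.1 (r from 0.157 to 0.278, against -0.245 to 0.183 in 12 other pairs), so for that comparison the blocked count is given beside the result. No other pair of groups met this. Within each tissue the 3 groups were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). The filter kept 38656 contigs in head kidney and 43072 in trunk kidney, and the biological coefficient of variation was 0.572 and 0.545. The tissue comparison and the differences of effects between tissues used all 24 libraries and 52407 contigs. The tissue comparison also required a change of more than 1 on the log2 scale. CPM in the text are TMM-scaled within the fit they belong to. The SE of a log2 fold change is its size divided by the square root of its F value. Log2 CPM for correlations and components used a prior count of 2. Contigs named were, for each comparison, the 2 higher and the 2 lower with the smallest p and a mean log2 CPM of at least 1, whether or not they passed the threshold. This rule was set before the data were examined, with a limit of 2 each way for identifiers without names.

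The number of contigs at equal depth was counted after thinning each library to 9000000 counts. Replicates were checked for duplicates, and the chi-square per degree of freedom between libraries of one group was 31.4 to 157.6, far above sampling noise. Where a group had 0 counts in a library, the limit given is that of 3 counts on the same TMM scale. Nothing in the labels says that the 4 libraries of a group came from separate tanks, so the p-values measure the spread between these libraries.

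On/off contigs were defined after the data were seen. Such a contig reached at least 1.5 log2 CPM in each tissue and had a gap of more than 3 on the log2 scale between neighbouring libraries in each tissue, with at least 2 libraries on each side. A head and a trunk library were called matched when each was the other's best partner and they were alike for at least 90% of the contigs. On simulated libraries of 8 shared fish the procedure returned 8 pairs, all 8 right. All 200 simulated contigs were drawn as on/off, with states independent between fish and between contigs. Fish of similar genotype were not simulated, so the result does not show how often they would be matched wrongly. Contigs at least 8 times higher in one tissue were picked, also after the data were seen, by setting the exposed group not compared against all libraries of the other tissue. In the results given no library was moved to another group. Fits with the labels of one tissue shifted in sample number order were looked at after the matching was seen and are not reported, because groups inferred from the data are not compared.

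In simulated counts for glyphosate in head kidney (38656 contigs), with 50 contigs changed at each size, the test recovered 2% at 2-fold, 54% at 4-fold, 76% at 8-fold and 96% at 16-fold. For Rodeo in trunk kidney (43072 contigs) it recovered 0%, 58%, 82% and 96%. Changes of 2-fold were thus rarely detected. The contigs of all sizes were changed in the same counts, and all had a mean log2 CPM of at least 1. Many true changes ease the adjusted threshold, so recovery would be lower where few contigs change. The shares therefore do not give the chance of detection in the real comparisons. Alternatives were another scaling, other filters on low counts, DESeq2 1.42.0, limma 3.58.1 with weights, with a random effect of the sample number carried by the deposited files or of the matched libraries, or with neither, the replicate number as a block, a fit of only the groups compared, and each library left out in turn.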

Results

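Messenger RNA was sequenced from the head kidney and the trunk kidney of adult male largemouth bass, a freshwater fish. In bony fish the head kidney makes blood and immune cells and holds steroid-producing interrenal cells, whereas the trunk kidney holds most of the nephrons. The fish had lived for 21 days in clean water, in water with glyphosate, a herbicide, or in water with Rodeo, a commercial glyphosate product. Both exposures were set at 10 mg/L of glyphosate. The lower dose of 0.5 mg/L was not analysed here. The 24 libraries formed 6 groups of 4, one for each tissue and treatment. Library totals ran from 9871623 counts in the third head control to 29858387 in the second trunk control. Trunk kidney libraries were deeper than head kidney libraries. In units of 1000000 counts, controls held 25.6 ± 3.15 in trunk and 16.8 ± 6.18 in head kidney (SD, n = 4 each). Counts were given for 78435 transcript contigs, sequences assembled from reads, and 0 of them could be paired with a gene name here. The contigs are therefore named by their identifiers, at most 2 in each direction for a comparison.

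The 2 tissues differed far more than the treatments did. The first principal component, which carried 62.4% of the variance, separated all 12 head kidney libraries from all 12 trunk kidney libraries. The Pearson correlation of log2 counts per 1000000 (CPM) across contigs had a median of 0.628 between libraries of different tissues. Between libraries of the same group it was 0.911 in head kidney and 0.919 in trunk kidney. Contigs are not independent replicates, so these values describe likeness only.

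**Figure D1:**
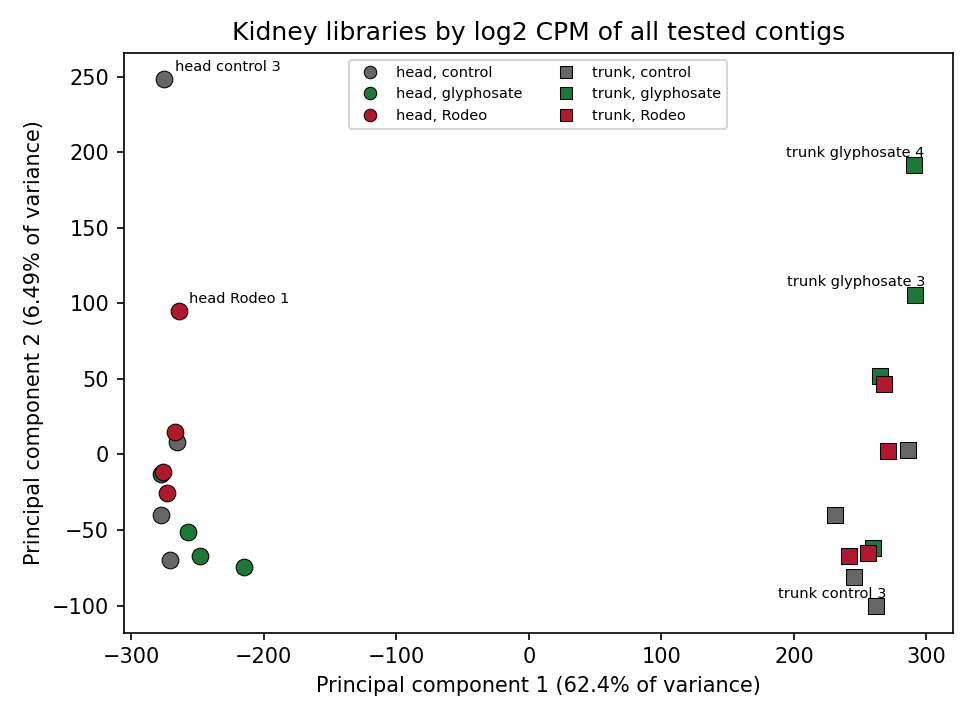
Principal components 1 (62.4% of variance) and 2 (6.49% of variance) of the log2 CPM of all tested contigs, with 1 point per library, circles for head kidney and squares for trunk kidney. The tissues separate along component 1, and head control 3 and trunk glyphosate 4 lie farthest along component 2 at 248.2 and 191.2.

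Control libraries of the 2 tissues, by the labels as given, were compared to describe what distinguishes them. No label gives the sequencing run, so a difference of run between the tissues could not be told apart from tissue. The contig isotig128247 stood at 59.5 ± 11.1 CPM in trunk controls and 0.0487 ± 0.0381 CPM in head controls (SD, n = 4 each; edgeR adjusted p = 2.49e-13). LMB_Assem.0.C246 stood at 205 ± 38.0 CPM in trunk controls against 2.1 ± 0.353 CPM in head controls (log2 fold change 6.59, SE 0.316; edgeR adjusted p = 1.14e-12). In the other direction, contig56602 stood at 489 ± 96.5 CPM in head controls and 12.2 ± 4.35 CPM in trunk controls. LMB_Assem.4362.C1 stood at 178 ± 14.1 CPM in head controls and 12.3 ± 3.37 CPM in trunk controls. All 4 libraries of each tissue lay apart from those of the other for these 4 contigs. In edgeR's quasi-likelihood test 22141 of 52407 contigs passed an adjusted p of 0.05 with a change of more than 1 on the log2 scale. Of these, 14569 were higher in trunk kidney and 7572 in head kidney. The imbalance grew with the size of the change, to 4850 against 302 contigs at more than 64-fold. Contigs higher in trunk kidney made up 54.1% of the counts of trunk controls and 12.6% of those of head controls. Contigs higher in head kidney made up 37.0% of the counts of head controls and 6.49% of those of trunk controls.

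Some contigs, picked without regard to treatment, were abundant in several libraries and close to absent in others. In 95 of them the libraries fell into a high and a low set in both tissues, with a gap of at least 8-fold between the sets. The pattern over these 95 on/off contigs was compared between each head and each trunk library, 144 pairs in all. In 8 pairs it was alike for between 95.8% and 100% of the contigs. The other 136 pairs were alike for at most 85.3%, with a median of 52.6%. Pairs of libraries from the same tissue reached at most 85.3% in head kidney and 83.2% in trunk kidney. In 0 of the 8 matched pairs did the head and the trunk library carry the same treatment label. Head control 2 matched trunk glyphosate 4, while head controls 3 and 4 matched trunk Rodeo 1 and 2. Head glyphosate 1, 3 and 4 matched trunk Rodeo 4, trunk control 1 and trunk control 2. Head Rodeo 1 and 3 matched trunk control 3 and trunk glyphosate 1. The 12 head and trunk libraries that share a treatment and a replicate number in their labels were alike for a median of 44.2%. The comparisons of treatments use the labels as given, so each group is the set of libraries labelled as control, glyphosate or Rodeo.

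**Figure D2:**
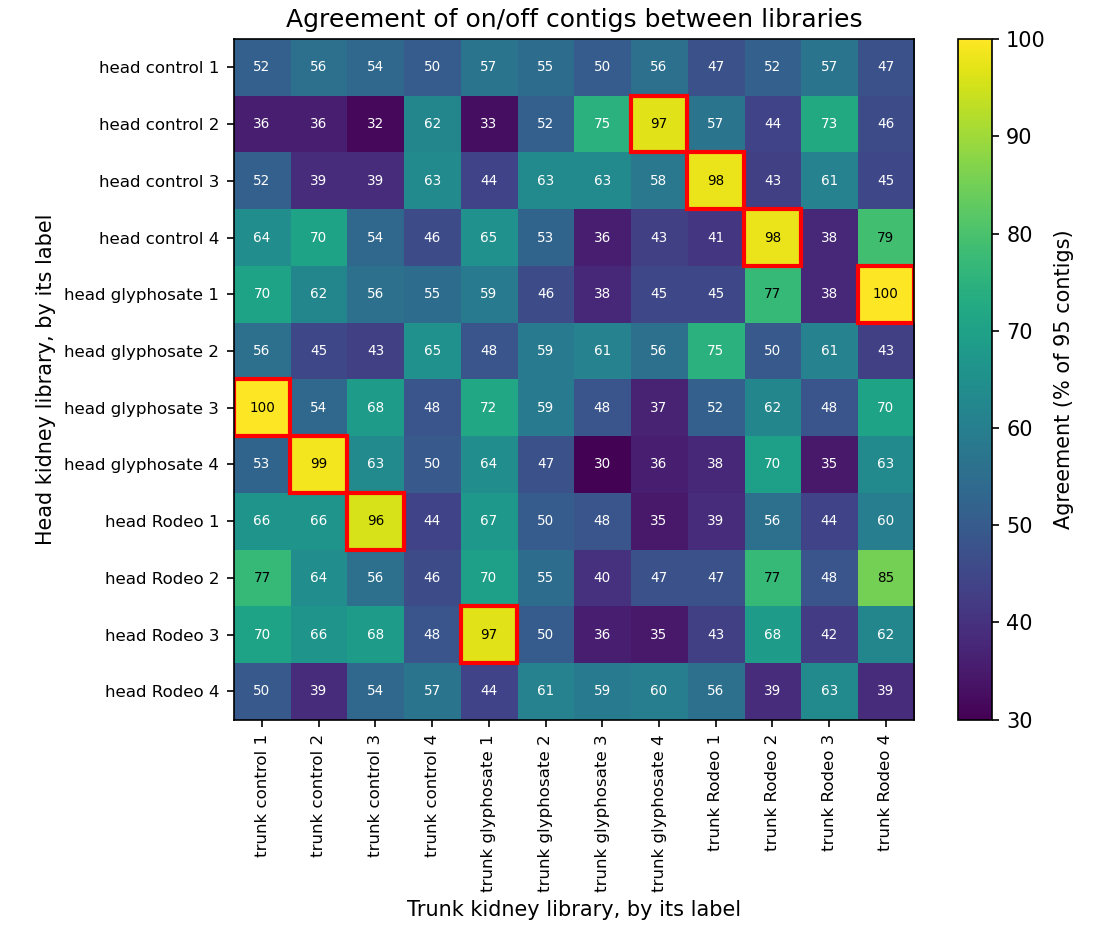
Percentage of the 95 on/off contigs for which a head kidney library (vertical axis) and a trunk kidney library (horizontal axis), each named by its label, were on the same side. Red frames mark the 8 pairs at 95.8% to 100%, which all join different treatment labels, while the other 136 pairs reached at most 85.3%.

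Trunk kidney libraries labelled Rodeo differed from those labelled control in a small set of contigs. LMB_Assem.6831.C1 fell from 86.3 ± 26.6 CPM in controls to 13.5 ± 2.88 CPM with Rodeo (log2 fold change -2.68, SE 0.27, n = 4 each; edgeR adjusted p = 0.00434). LMB_Assem.6761.C1 fell from 101 ± 23.7 CPM to 20.3 ± 4.46 CPM (log2 fold change -2.32, SE 0.262; edgeR adjusted p = 0.00729). LMB_Assem.10888.C1 rose from 3.05 ± 0.524 CPM to 15.4 ± 2.92 CPM (log2 fold change 2.34, SE 0.292; edgeR adjusted p = 0.0118). LMB_Assem.3657.C1 rose from 4.23 ± 0.885 CPM to 19.8 ± 3.46 CPM (log2 fold change 2.22, SE 0.278; edgeR adjusted p = 0.0118). For all 4 contigs each of the 4 Rodeo libraries lay beyond each of the 4 controls. Of 43072 contigs tested with edgeR, 8 passed the adjusted threshold, 2 higher and 6 lower with Rodeo. The number with an unadjusted p under 0.05 was 1998, against 2154 that chance would give. DESeq2 called 59 contigs, 19 higher and 40 lower, including all 8. Leaving out the fourth Rodeo library reduced the edgeR count to 1, LMB_Assem.6831.C1. Over 16 fits with a library left out or another setting, LMB_Assem.10888.C1 lost the threshold in 7 and LMB_Assem.3657.C1 in 5. LMB_Assem.6761.C1 lost it in 2 and LMB_Assem.6831.C1 in 1, and all 4 kept their direction. Among the trunk libraries matched to no head library, 1 control and 1 Rodeo library with the spread taken from 2 glyphosate libraries, 192 contigs passed and 0 of the 8 were among them. There LMB_Assem.6831.C1 differed by -3.06 (SE 1.0), LMB_Assem.6761.C1 by -2.87 (SE 0.987), LMB_Assem.10888.C1 by 2.42 (SE 1.14) and LMB_Assem.3657.C1 by 2.14 (SE 1.11), changes of similar size with a larger SE. The same control and Rodeo library had helped to pick these contigs, so changes in that direction were built in and are no separate support. The count also fell by more than 1.5 times without trunk control 1 (3 contigs), control 3 (5), control 4 (3), Rodeo 2 (2) or Rodeo 3 (4).

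The trunk libraries labelled glyphosate lay between controls and Rodeo for all 8 of these contigs. LMB_Assem.6831.C1 stood at 37.3 ± 4.18 CPM and LMB_Assem.6761.C1 at 57.6 ± 11 CPM with glyphosate. LMB_Assem.10888.C1 stood at 6.16 ± 1.73 CPM and LMB_Assem.3657.C1 at 8.05 ± 2.07 CPM (SD, n = 4). Against controls, the glyphosate libraries differed by -1.21 on the log2 scale for LMB_Assem.6831.C1 (SE 0.257) and by 1.02 for LMB_Assem.10888.C1 (SE 0.284). Neither change passed the threshold (edgeR adjusted p = 0.461 for both). These contigs were followed because they differed between libraries labelled Rodeo and control, so they are not an independent test of glyphosate.

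**Figure D3:**
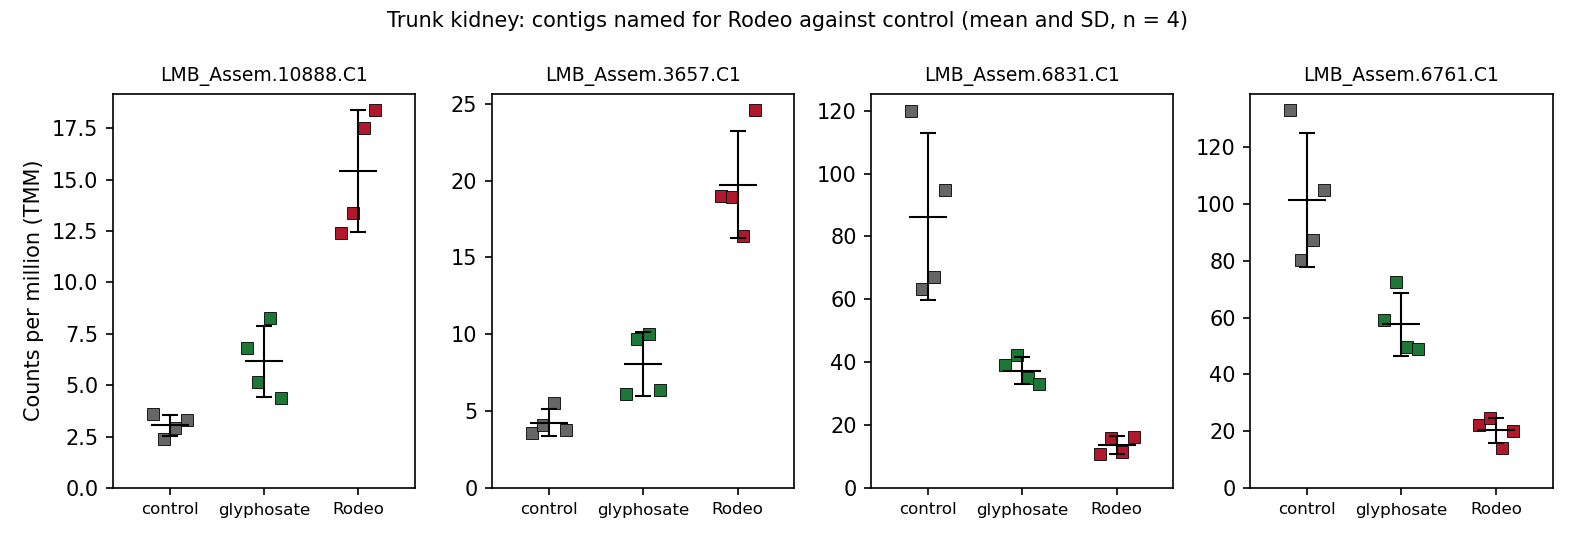
CPM after trimmed-mean (TMM) scaling of the 4 contigs named for Rodeo against control in trunk kidney, with 1 square per library, a horizontal bar for the group mean and whiskers of 1 SD (n = 4). The Rodeo libraries stand apart from the controls in each panel, and the glyphosate means lie between them, for example 37.3 CPM between 86.3 and 13.5 for LMB_Assem.6831.C1.

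For trunk kidney libraries labelled glyphosate against those labelled control, no contig passed the adjusted threshold in edgeR. The contig with the smallest p among those higher was isotig90068, at 22.9 ± 6.61 CPM with glyphosate and 6.45 ± 1.54 CPM in controls (log2 fold change 1.83, SE 0.287; edgeR adjusted p = 0.324). LMB_Assem.5280.C1 stood at 486 ± 29.9 CPM with glyphosate and 178 ± 45.4 CPM in controls (log2 fold change 1.45, SE 0.274; edgeR adjusted p = 0.461). Among those lower, isotig75858 stood at 0.0425 ± 0.0501 CPM with glyphosate and 5.81 ± 1.94 CPM in controls (edgeR adjusted p = 0.324). LMB_Assem.6686.C2 stood at 2.02 ± 1.07 CPM with glyphosate and 12.6 ± 4.37 CPM in controls (log2 fold change -2.63, SE 0.477; edgeR adjusted p = 0.461). Each of the 4 glyphosate libraries lay beyond all 4 controls for these contigs. The unadjusted p was under 0.05 for 4521 contigs, where chance would give 2154 on average, and DESeq2 called 146 contigs, 89 higher and 57 lower. Of 35 splits of these libraries, the real one included, 7 reached 4521 and the highest had 8644. The excess over 2154 therefore does not argue against chance. Trunk glyphosate libraries held 50146 ± 6309 contigs at an equal depth of 9000000 counts, against 57220 ± 3551 in trunk controls. That difference did not pass an exact two-sided permutation test (p = 0.086, and 0.86 after adjustment over 12 such comparisons). The 615 contigs at least 8 times higher in head kidney had a mean log2 CPM of 0.731 ± 0.297 in trunk glyphosate libraries. In trunk controls it was 1.19 ± 0.385 (SD, n = 4, exact two-sided permutation p = 0.14 before adjustment).

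The 2 products were also compared with each other, glyphosate being the ingredient that Rodeo contains. In trunk kidney, LMB_Assem.6616.C1 stood at 9.54 ± 0.997 CPM in libraries labelled Rodeo and 57.0 ± 25.4 CPM in those labelled glyphosate (log2 fold change -2.58, SE 0.356; edgeR adjusted p = 0.101). LMB_Assem.11835.C1 stood at 0.558 ± 0.293 CPM with Rodeo and 6.10 ± 1.71 CPM with glyphosate (log2 fold change -3.46, SE 0.525; edgeR adjusted p = 0.101). In the other direction, isotig75858 stood at 4.31 ± 3.06 CPM with Rodeo and isotig89478_0 at 7.76 ± 8.20 CPM. With glyphosate these stood at 0.0425 ± 0.0501 and 0.107 ± 0.136 CPM. No contig passed the adjusted threshold in edgeR, 3294 had an unadjusted p under 0.05, and DESeq2 called 374. With the replicate number as a block edgeR called 1 contig, lower with Rodeo. Without trunk glyphosate 1 the edgeR count was 38, of which 36 were lower with Rodeo, and without trunk Rodeo 3 it was 1.

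In head kidney no contig passed the adjusted threshold between libraries labelled glyphosate and libraries labelled control. Among the contigs with the smallest p, isotig104779 stood at 15.1 ± 2.08 CPM with glyphosate and 31.1 ± 5.58 CPM in controls (log2 fold change -1.04, SE 0.241; edgeR adjusted p = 0.761). The contig contig34835 stood at 34.8 ± 6.23 CPM with glyphosate and 76.7 ± 30.2 CPM in controls (log2 fold change -1.14, SE 0.272; edgeR adjusted p = 0.761). Higher values were seen for LMB_Assem.12773.C1, at 49.2 ± 79.0 CPM with glyphosate and 0.0929 ± 0.12 CPM in controls. LMB_Assem.0.C339 stood at 11 ± 9.83 CPM with glyphosate and 0.063 ± 0.126 CPM in controls (edgeR adjusted p = 0.761 for both). For these latter contigs 3 of the 4 glyphosate libraries lay above all controls, and the SD was close to or above the mean. LMB_Assem.12773.C1 was abundant in trunk kidney, at 1070 to 4860 CPM. The 1805 contigs at least 8 times higher in trunk kidney had a mean log2 CPM of 1.52 ± 0.328 in head glyphosate libraries and 1.23 ± 0.214 in head controls (SD, n = 4; exact two-sided permutation p = 0.26, and 0.52 after adjustment over 6 such tests). The unadjusted p was under 0.05 for 2481 of 38656 contigs in edgeR, against 1933 by chance on average, and DESeq2 called 35. Of 35 splits of these libraries, the real one included, 7 reached 2481, so that excess does not argue against chance. Without head glyphosate 1 the edgeR count was 1.

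Head kidney libraries labelled Rodeo did not differ from those labelled control past the threshold either. LMB_Assem.3527.C1 stood at 6.34 ± 3.03 CPM with Rodeo and 0.758 ± 0.425 CPM in controls (log2 fold change 3.05, SE 0.587; edgeR adjusted p = 0.923). The contig contig23756 stood at 253 ± 188 CPM with Rodeo and 2.22 ± 2.51 CPM in controls, with 3 of 4 Rodeo libraries above all controls. It is one of the 95 on/off contigs. In trunk kidney it stood at 165 to 232 CPM in control 3, glyphosate 1, glyphosate 3 and Rodeo 3 and at most at 5.53 CPM in the others. The high head Rodeo libraries 1 and 3 are those matched to trunk control 3 and trunk glyphosate 1. LMB_Assem.9524.C1 stood at 9.34 ± 5.33 CPM with Rodeo and 123 ± 60.1 CPM in controls (log2 fold change -3.72, SE 0.805; edgeR adjusted p = 0.923). Also lower was isotig131305, at 0.598 ± 0.353 CPM with Rodeo and 9.30 ± 4.77 CPM in controls (log2 fold change -3.97, SE 0.86; edgeR adjusted p = 0.923). Of these, LMB_Assem.9524.C1 stood at 489 to 1230 CPM in trunk kidney, isotig131305 at 71.9 to 300 CPM and LMB_Assem.3527.C1 at 19.2 to 52.3 CPM, above all head libraries. The 1559 contigs at least 8 times higher in trunk kidney had a mean log2 CPM of 1.12 ± 0.0529 in head Rodeo libraries and 1.11 ± 0.164 in head controls (SD, n = 4; exact two-sided permutation p = 0.94, and 0.94 after adjustment). The unadjusted p was under 0.05 for 1817 contigs in edgeR, against 1933 by chance, and DESeq2 called 73, of which 52 were lower. Without head Rodeo 2 the edgeR count was 2.

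Between head libraries labelled Rodeo and those labelled glyphosate, LMB_Assem.1991.C1 stood at 79.4 ± 12.4 against 29.9 ± 3.66 CPM (log2 fold change 1.41, SE 0.21; edgeR adjusted p = 0.225). LMB_Assem.12144.C1 stood at 5.71 ± 1.75 against 38.8 ± 22.7 CPM (log2 fold change -2.76, SE 0.458; edgeR adjusted p = 0.262). The contig contig23756 stood at 253 ± 188 CPM with Rodeo against 0.251 ± 0.363 CPM with glyphosate (edgeR adjusted p = 0.262). LMB_Assem.9524.C1 stood at 9.34 ± 5.33 against 143 ± 93.1 CPM (edgeR adjusted p = 0.451), and 0 of the Rodeo libraries lay beyond all glyphosate libraries. No contig passed the threshold in edgeR, 3538 had an unadjusted p under 0.05, and DESeq2 called 147. Without head glyphosate 4 the edgeR count was 20, of which 19 were lower with Rodeo, and without head Rodeo 2 it was 2.

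Contigs with such a gap in the tissue compared, whether or not they had one in the other tissue, were counted among the largest differences. Among contigs with an unadjusted p under 0.05, a mean log2 CPM of at least 1 and a change of more than 16-fold, they made up 46.0% of 50 for glyphosate against control in head kidney and 15.6% of 64 in trunk kidney. For Rodeo against control the shares were 40.6% of 32 and 50.0% of 18, and for Rodeo against glyphosate 33.3% of 63 and 18.2% of 66. A gap of more than 8-fold is part of their definition, so large changes are partly built in. Of all tested contigs at that mean level they were 0.952% in head kidney and 0.723% in trunk kidney.

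Whether an exposure acted differently in the 2 tissues was tested as the difference of the effects, head minus trunk, over all 24 libraries. By the labels as given, the Rodeo effect on LMB_Assem.6831.C1 differed by 3.55 on the log2 scale (SE 0.506, edgeR adjusted p = 0.0095). In head kidney this contig stood at 27.2 ± 11.7 CPM in controls and 49.8 ± 17.2 CPM with Rodeo, while in trunk kidney, on the same scale, it stood at 103 ± 31.5 and 16 ± 3.41 CPM. For LMB_Assem.6761.C1 the difference was 3.09 (SE 0.449; edgeR adjusted p = 0.0095), with 23.1 ± 3.11 and 39.3 ± 12.6 CPM in head kidney. In the other direction LMB_Assem.10888.C1 differed by -3.41 (SE 0.608; edgeR adjusted p = 0.0706). The contig contig09977 (edgeR adjusted p = 0.0706) stood at 0.14 ± 0.0824 CPM in trunk controls, with at most 5 counts in a library, and at 6.81 ± 6.48 CPM with Rodeo. In head kidney it stood at 0.794 ± 0.478 and 0.264 ± 0.0716 CPM. In all, 3 of 52407 contigs passed the threshold in edgeR, each with a higher value for head minus trunk, 3165 had an unadjusted p under 0.05, and DESeq2 called 127. These differences join head and trunk groups whose matched libraries carried different treatment labels. Without the matched head libraries edgeR called 0 contigs, with 3272 at an unadjusted p under 0.05, and without the matched trunk libraries 0, with 1311. The differences were then 3.29 (SE 0.627) and 3.95 (SE 0.917) for LMB_Assem.6831.C1 and 2.64 (SE 0.6) and 3.65 (SE 0.809) for LMB_Assem.6761.C1. The libraries kept had helped to pick these contigs, so differences in that direction were built in and are no separate support.

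For glyphosate no difference of effects passed the threshold in edgeR, 6292 contigs had an unadjusted p under 0.05, and DESeq2 called 209. LMB_Assem.5280.C1 stood at 34.7 ± 5.74 CPM with glyphosate and 54.8 ± 13.6 CPM in controls in head kidney. In trunk kidney it stood at 575 ± 35.6 and 212 ± 53.7 CPM (difference -2.1 on the log2 scale, SE 0.413; edgeR adjusted p = 0.224). LMB_Assem.3183.C3 stood at 20.2 ± 4.16 and 40.0 ± 9.96 CPM in head kidney and at 39.1 ± 8.53 and 19.1 ± 4.72 CPM in trunk kidney (difference -2.02, SE 0.378; edgeR adjusted p = 0.173). LMB_Assem.0.C9113 differed in the other direction by 3.73 (SE 0.699; edgeR adjusted p = 0.173), with 7.22 ± 2.23 CPM in trunk controls and 1.46 ± 0.759 CPM with glyphosate. LMB_Assem.10270.C1 was at 0 counts in all 4 head controls, which allows up to 0.283 CPM in the shallowest of them, and at 0.583 ± 0.536 CPM with glyphosate, against 33 ± 6.06 and 24 ± 3.18 CPM in trunk kidney (edgeR adjusted p = 0.0734). Without trunk glyphosate 1 the edgeR count was 7, and without head glyphosate 1 it was 3.

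The changes with glyphosate and with Rodeo were set against each other across contigs. Their log2 fold changes correlated at a Pearson r of 0.495 in head kidney and 0.437 in trunk kidney. Both changes share the same control libraries, and groups simulated with no effect gave 0.504 and 0.492. The simulated libraries were independent, so the joint deviations of same-numbered trunk glyphosate and trunk Rodeo libraries were left out. The covariance was 0.25 against 0.203 simulated in head kidney and 0.199 against 0.178 in trunk kidney. When each product was set against a different pair of controls, r averaged -0.047 in head kidney and 0.073 in trunk kidney over the 6 ways to split them. Contigs are not independent replicates, and leaving out single libraries gave a jackknife SE of 0.23 and 0.24 for r.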

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

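The tests of the matched pairs, those of the 8 trunk kidney contigs, the fits without the matched libraries or with them as a random effect, the counts of splits within a tissue and all counts of splits at an unadjusted p were chosen after the results were seen, whereas the other splits across tissues were set before.

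In 8 pairs a head kidney library matched a trunk kidney library of another treatment label by its on/off contigs. Different fish of similar genotype would need equally close pairs within a tissue, and on/off contigs that follow the exposure would make fish of one exposure there as alike whatever the labels, but the closest pair within a tissue reached 85.3% and the lowest matched pair 95.8%. A candidate explanation is that libraries of one tissue carry the wrong labels. It was examined in the 8 contigs that differed between trunk libraries labelled Rodeo and control, which are not on/off. In these, matched head and trunk libraries differed by 0.476 on the log2 scale after centring, against a median of 0.968 over all 40320 pairings (exact one-sided permutation p = 0.013). Which tissue would carry wrong labels stays open. In the order of the sample numbers that the deposited files carry, all 8 matched pairs lay 6 of 12 places apart. Of the matched libraries, 8 of 8 in trunk and 6 of 8 in head kidney carry a number found in both tissues, but nothing states that the numbers are fish. The 8 head and trunk pairs with the same number were alike for a median of 45.3% of the on/off contigs. In the 8 contigs they differed by 1.33 on the log2 scale after centring, against a median of 0.962 over all pairings (exact one-sided permutation p = 0.99). The mean log2 CPM of the 8 contigs, signed by their direction with Rodeo, runs in trunk kidney the way the labels say (control -4.07 to -3.63, glyphosate -2.83 to -2.72, Rodeo -1.7 to -1.43). Head control (-1.27 to -0.153) and head Rodeo (-2.04 to -1.36) were also apart, in the opposite order, while head glyphosate ran from -1.96 to -0.651. The trunk labels chose the contigs, however. Over contigs called without the trunk glyphosate libraries, these libraries ranged over 1.7, between control and Rodeo libraries 2.88 apart.

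The 8 contigs that differed in trunk kidney between Rodeo and control, with glyphosate between, form another pattern. Of the 35 splits of those 8 libraries only the real one gave as many contigs (1 of 35, with 8 against at most 1 elsewhere). That share argues against a chance split for that count but cannot exclude it. It is the smallest share possible and was not adjusted for the other comparisons. The count fell to between 1 and 5 without trunk control 1, 3 or 4 or trunk Rodeo 2, 3 or 4 (1 without Rodeo 4). At an unadjusted p under 0.05, 8 of 35 splits reached the real 1998 contigs (highest other 2910). That glyphosate lay between in 8 of 8 contigs adds little, since contigs picked for a difference between 2 groups tend to place another group between them. The 8 also moved together across libraries, so they are not separate cases. Picking them for the same difference between groups partly builds this in, and likeness within groups was not examined. More or less head-kidney-like tissue in the Rodeo pieces would move the contigs higher in head kidney by at least 1.85, the smallest of the 8 changes, but their mean moved by -0.045 (SD 0.362 in controls). The order or time of sampling was not tested, as no label gives it; an effect of the exposure itself, which the design names, stays open and untested beyond the comparison.

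By the labels as given, the Rodeo effect differed between the tissues (head minus trunk, log2) by 3.55 for LMB_Assem.6831.C1, 3.09 for LMB_Assem.6761.C1 and 2.87 for 1 further contig. Of 30 splits drawn, 1 gave as many contigs, the real one, with 3 against at most 1 elsewhere. That share is the smallest possible and was not adjusted for the other comparisons. It also takes head and trunk libraries as independent, which the 8 matched pairs put in doubt, so a chance split is not excluded. At an unadjusted p under 0.05, 4 of 30 splits reached the real 3165 (highest other 5501). With the matched libraries as a random effect (estimated correlation 0.038) limma-voom called 6 contigs, including these 3, as it did with no random effect. Without the matched head libraries edgeR called 0 contigs (3272 at an unadjusted p under 0.05) and without the matched trunk libraries 0 (1311), where DESeq2 called 127 in all 24 libraries. A wrong label in one tissue would change what these differences compare, and could change their sign. Groups inferred from the data are not compared, so a change of sign was not tested. Opposite effects of Rodeo in the tissues are thus not established. For control libraries, 1 of 35 splits of the 8 libraries gave 22141 contigs between trunk and head kidney, the real one, and the highest other gave 0.

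In the other comparisons edgeR called 0 contigs (DESeq2 35 to 374), a count that 35 of 35 splits within a tissue and 30 of 30 across tissues must reach, so it decides nothing about chance. The counts at an unadjusted p under 0.05 do vary. For glyphosate against control, 7 of 35 splits reached the real 2481 in head kidney and 7 of 35 the real 4521 in trunk kidney, with at most 14 and 74 contigs past the threshold in another split. For Rodeo against control in head kidney, 15 of 35 reached 1817 (at most 8 past the threshold). For Rodeo against glyphosate, only the real split of 35 reached 3538 in head kidney (highest other 2797), where another split had 125 contigs past the threshold. A single split of 35 is the smallest share possible and was not adjusted for the other comparisons. In trunk kidney 5 of 35 reached 3294 (at most 6 past the threshold). Of the 8 splits that part all 4 same-numbered pairs only the real one did (highest other 2270), but a single split of 8 is too large a share to argue against chance. For the glyphosate effect between tissues, 2 of 30 reached 6292 (at most 4 past the threshold). The split with 74 contigs set trunk control 1 and trunk glyphosate 2, 3 and 4 against the rest. The one with 125 set head glyphosate 1, 2 and 3 and head Rodeo 4 against the rest. Each exchanged 1 library for 1 of the other group. Each was the highest of 35 splits in its comparison, and what raised its count was not tested.

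In 50 groups of 4 values checked, 5 had a library far from the others, where chance would give 2.5. The second trunk Rodeo library had 27.39 in units of 1000000 counts, and the first head glyphosate library had 45192 contigs at equal depth. Single contigs stood apart at 0.252 CPM in head control 2 for LMB_Assem.0.C339, at 1.2 CPM in head Rodeo 2 for the on/off contig contig23756 and at 2.97 CPM in trunk control 2 for isotig75858.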

How the results depend on the processing

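The settings that kept only unmatched libraries, those of the on/off gap and contig class, and limma-voom with the matched libraries as a random effect or with none were chosen after the results were seen, and the others were planned. The same 8 pairs were each other's best partners at gaps of 1.5, 2, 2.5 and 3 on the log2 scale, in LMB_Assem contigs alone and in isotig and contig classes pooled. With all classes pooled, their lowest agreement fell to 86.2% at a gap of 2 and 80.2% at 1.5, below the 90% required of a match (other pairs at most 78.4% and 72.1%). In LMB_Assem contigs alone it was already 89.5% at a gap of 2.5 and 84.4% at 2 (other pairs at most 86.8% and 78.1%). In isotig and contig classes it fell to 79.8% at 1.5 (other pairs at most 75.5%). Of named contig results past the threshold, 85 with 1 library left out and 84 under other settings stayed, 11 and 8 lost it. Of the others, 244 and 172 stayed, 12 and 44 passed, and no contig reversed. The tissue contigs had no losses and those for trunk Rodeo up to 7 in 16 settings. Another scaling (DESeq2 size factors in edgeR) and a minimum of 1 CPM in 4 libraries moved no count by more than 1.5 times. The gene list tests were not run, as the contigs carry no names. In simulated counts, 2-fold changes were recovered in 2% and 0% of contigs. The cause was not tested for any count that moved, except that fewer libraries entered where stated.

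Contigs past the threshold, in the order glyphosate against control, Rodeo against control and Rodeo against glyphosate, were 75, 27 and 143 in head kidney without a filter on low counts, and 3 in trunk kidney for Rodeo against glyphosate. With DESeq2 they were 35, 73 and 147 in head kidney and 146, 59 and 374 in trunk kidney, and 209 and 127 for the glyphosate and Rodeo effects between tissues. With the replicate number as a block, glyphosate and Rodeo against control in head kidney each had 1 and Rodeo against glyphosate in trunk kidney had 1. The block changed no other count by more than 1.5 times. Same-numbered libraries deviated together between trunk glyphosate and trunk Rodeo alone. With only the groups compared in the fit, Rodeo against control in head kidney had 3. With limma-voom and quality weights, Rodeo against control in trunk kidney had 19, including all 8. With the sample number as a random effect in limma-voom, the glyphosate effect between tissues had 2. With the matched libraries as a random effect, and also with none, limma-voom gave 2 and 6 for the glyphosate and Rodeo effects between tissues.

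With only the head libraries matched to no trunk library (1 control, 1 glyphosate and 2 Rodeo libraries), the counts in head kidney were 186, 55 and 291. The glyphosate and Rodeo effects between tissues then had 15 and 0, and the tissue comparison 11843. With only the trunk libraries matched to no head library (1 control, 2 glyphosate and 1 Rodeo library), the counts in trunk kidney were 250, 192 and 158, and the others 1, 0 and 10189. In the fits within a tissue the spread rests on a single pair of libraries, and a lone library is assumed to vary like it. LMB_Assem.6831.C1 differed by -3.06 (SE 1.0) between the 1 trunk control and the 1 trunk Rodeo library, both of which had helped to pick it.

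With controls split, r between the responses averaged -0.0473 in head and 0.0734 in trunk kidney. Leaving out 1 library at a time gave, in head kidney, 0 to 1 contigs for glyphosate, 0 to 2 for Rodeo and 0 to 20 for Rodeo against glyphosate. In trunk kidney it gave 0 in all 8 fits for glyphosate, 1 to 8 for Rodeo and 0 to 38 for Rodeo against glyphosate. It gave 0 to 7 and 2 to 4 for the glyphosate and Rodeo effects between tissues, 20554 to 21905 between tissues, and r of 0.376 to 0.626 in head and 0.327 to 0.544 in trunk kidney. The highest counts came without head glyphosate 1 (1), head Rodeo 2 (2), head glyphosate 4 (20) and trunk glyphosate 1 (38 and 7), and the lowest for Rodeo in trunk kidney without trunk Rodeo 4 (1).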
